A study of Mus musculus with 32 samples.

How the data were processed

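The samples were RNA-seq libraries of whole muscle and of sorted muscle cells from mice with an inducible DUX4 gene and from WT mice; the labels name doxycycline chow as the treatment of all 32 samples, WT included. Per the labels, 500 ng of RNA was used per whole-muscle library (KAPA mRNA kit), sorted samples held 75000 CD31+ or PDGFRa+ cells from hind limb muscle (NEBNext low-input cDNA and Nextera XT), and reads were paired and 50 bases long. Per the submitters' processing notes, Salmon 0.6.0, CASAVA 1.8 and the mm10 genome (GRCm38) were used, and the authors deposited 1 table per library of expected counts per Ensembl gene, that is, estimated counts not scaled to depth. The annotation release and the step from transcripts to genes are not given in the sources used here. Neither are the muscles taken, the time point of the sorted cells, the sex of the mice or whether each library came from a separate animal.

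Each table held 43035 genes, and 42459 of them were given a symbol from the GENCODE annotation of GRCm38 (release vM21). The counts were rounded to whole numbers and analysed with edgeR 4.0.16 in R 4.3.3. Whole-muscle libraries (18) and sorted-cell libraries (14) were fitted separately, each with 1 mean per group. Genes with low counts were removed by filterByExpr with its minimum of 10 counts, libraries were scaled by trimmed mean of M-values (TMM) factors, and a robust quasi-likelihood test gave each p-value, adjusted by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05. The SE of a log2 fold change is the change divided by the square root of its F statistic. CPM are TMM-normalised counts scaled to library size, except where values per library are given from totals alone. Totals ran from 6.07 to 20.7 M counts, so that a count of 0 allowed 0.494 to 0.145 CPM, taking 3 counts per library as the limit.

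DUX4 was compared with WT in whole muscle at 2 weeks, in whole muscle at 16 weeks, in endothelial cells and in FAPs. Interaction terms compared the DUX4 effect between the times and between the cell types. Replicates were numbered in order of accession, which gives no pairing, so no paired analysis was possible. The comparisons, 37 gene lists with 545 genes drawn up from background knowledge, the rule for naming genes and the first set of alternative settings were fixed before the data were examined. Of the list genes 7 matched no entry. The number of genes given for a fixed list in a comparison is the number tested, which can be smaller than the list. Each list with at least 3 tested members was tested with camera (limma 3.58.1) at its preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the lists of a comparison. The list of early-embryo genes controlled by mouse Dux had fewer than 3 tested members in each comparison and was not tested. The term adjusted over the list alone means that the Benjamini-Hochberg adjustment was repeated within the list. Lists of kidney genes and of genes that mark position in the body were written after the calls had been seen. Overlaps of calls were set against the number for independent calls.

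Named genes were, in each DUX4 comparison, the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 CPM in the higher group and an established symbol; up to 2 called members with the smallest p of each list; and all tested members of the DUX4-responsive and FSHD-homologue lists. For each interaction the 4 largest differences in each direction were named. Sex-linked genes and immunoglobulin variable segments were left out of the ranking, and the text prints a part of the genes named by this rule. Positions on GRCm38 of some lead genes are chromosome 2, 164731180 to 164745931 (Wfdc3, ENSMUSG00000076434), chromosome 3, 60025717 to 60040160 (Aadac, ENSMUSG00000027761), chromosome 11, 94936224 to 94953042 (Col1a1, ENSMUSG00000001506), chromosome 19, 34640871 to 34650009 (Ifit1, ENSMUSG00000034459), chromosome 17, 14279506 to 14404790 (Smoc2, ENSMUSG00000023886), chromosome 12, 85166635 to 85177790 (Pgf, ENSMUSG00000004791) and chromosome 15, 96994820 to 97055956 (Slc38a4, ENSMUSG00000022464).

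These alternative settings were DESeq2 1.42.0 (Wald test), limma voom with quality weights, relative log expression size factors, no low-count filter and a stricter one, a minimum fold change of 2, only the 2 groups compared, a covariate from Y-linked counts, unadjusted p under 0.01 for the overlaps, and leaving out each library in turn. Alternatives added after the data were seen were a term for 2 sets of 2-week libraries, each set alone, leaving out WT.16Weeks replicates 1 and 4 together, and restrictions of the endothelial and FAP calls by gene. For a test of depth, counts were thinned to the lowest total with edgeR. The procedure was tested on simulated negative binomial counts with the mean levels, library sizes and spread of the real libraries, to which changes of known size were added. edgeR recovered 60.6% of 2-fold and 84% of 4-fold changes at 2 weeks with 7.1% false calls, 32% and 72.7% at 16 weeks with 2.8%, 14.4% and 54.2% in endothelial cells with 7.04%, and 19.8% and 42.4% in FAPs with 4.92%. DESeq2 gave 16%, 14.8%, 26.9% and 29% false calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No library was left out of the reported fits.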

Results

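RNA was sequenced from mice carrying an inducible gene for DUX4, the transcription factor whose misexpression in muscle underlies facioscapulohumeral dystrophy (FSHD), and from wild-type (WT) mice. The 32 libraries formed 8 groups, each named as in the labels. Whole muscle at 2 weeks gave 5 DUX4 libraries (IDUX.2Weeks) and 5 WT libraries (WT.2Weeks), and whole muscle at 16 weeks gave 4 of each (IDUX.16Weeks, WT.16Weeks). Endothelial cells sorted on CD31 gave 4 DUX4 libraries (CD31DUX) and 3 WT libraries (CD31WT). Fibro-adipogenic progenitors (FAPs), the connective tissue cells of muscle, were sorted on PDGFRa and gave 4 DUX4 libraries (PDGDUX) and 3 WT libraries (PDGWT). Total counts per library ranged from 6071276 or 6.07 M (IDUX.16Weeks replicate 2) to 20666816 or 20.7 M (CD31DUX replicate 4). They were 12.8 to 14.1 M in IDUX.2Weeks, 10.6 to 17.8 in WT.2Weeks, 6.07 to 19 in IDUX.16Weeks and 6.78 to 19.4 in WT.16Weeks. In the sorted cells they were 15.7 to 20.7 M in CD31DUX, 15.2 to 17.2 in CD31WT, 11 to 13.7 in PDGDUX and 16.6 to 18.9 in PDGWT. A count of 0 allowed up to 0.145 CPM, the count scaled to the library total, in the deepest library and up to 0.494 in the shallowest, a limit that covers counting error only. The p-values below measure spread between these libraries, since nothing in the labels says that each came from a separate animal. The human DUX4 transgene had no entry in the gene table and was not analysed here. Its mouse counterpart Duxf3 reached at most 0.116 CPM in any library.

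The comparison at 2 weeks asked how whole muscle with DUX4 differed from WT muscle early in the course of the disease. Wfdc3, which encodes a secreted protease inhibitor and responds to DUX4 in mouse muscle cells, stood at 65.2 ± 38.4 CPM (SD, n = 5) with DUX4 and 0.207 ± 0.209 CPM (n = 5) in WT muscle. That was a log2 difference of 8.14 ± 0.62 (SE, adjusted p = 3.07e-07). Sord, the gene for sorbitol dehydrogenase, rose from 69.3 ± 11.9 to 477 ± 120 CPM (log2 2.78 ± 0.17, adjusted p = 5.01e-08). All 6 tested genes of a fixed list of DUX4-responsive mouse genes rose, and 6 rose when adjusted over the list alone (median log2 2.63). Ilvbl rose by 2.49 ± 0.16, Slc15a2 by 2.05 ± 0.49 and Agtrap by 0.94 ± 0.27, the last losing its call without IDUX.2Weeks replicates 1, 2 or 5 or WT.2Weeks replicate 4 (adjusted p up to 0.0724). Serpinb6c, the remaining member, was at 3.07 ± 2.95 CPM against 0.0347 ± 0.0477. The list test gave an adjusted p of 2.94e-18, and 0.00656 with an estimated correlation. Genes without a count in any WT library were Aadac, an arylacetamide deacetylase (22.1 ± 10.5 CPM, at least 83.1-fold higher, on a floor of 3 counts per library), Teddm3 (at least 49.3-fold), the growth factor gene Areg (at least 38.3-fold) and the parathyroid hormone gene Pth (at least 26.9-fold). The angiotensin receptor gene Agtr2 was at 85.5 ± 50 CPM against 0.165 ± 0.321.

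**Figure D1:**
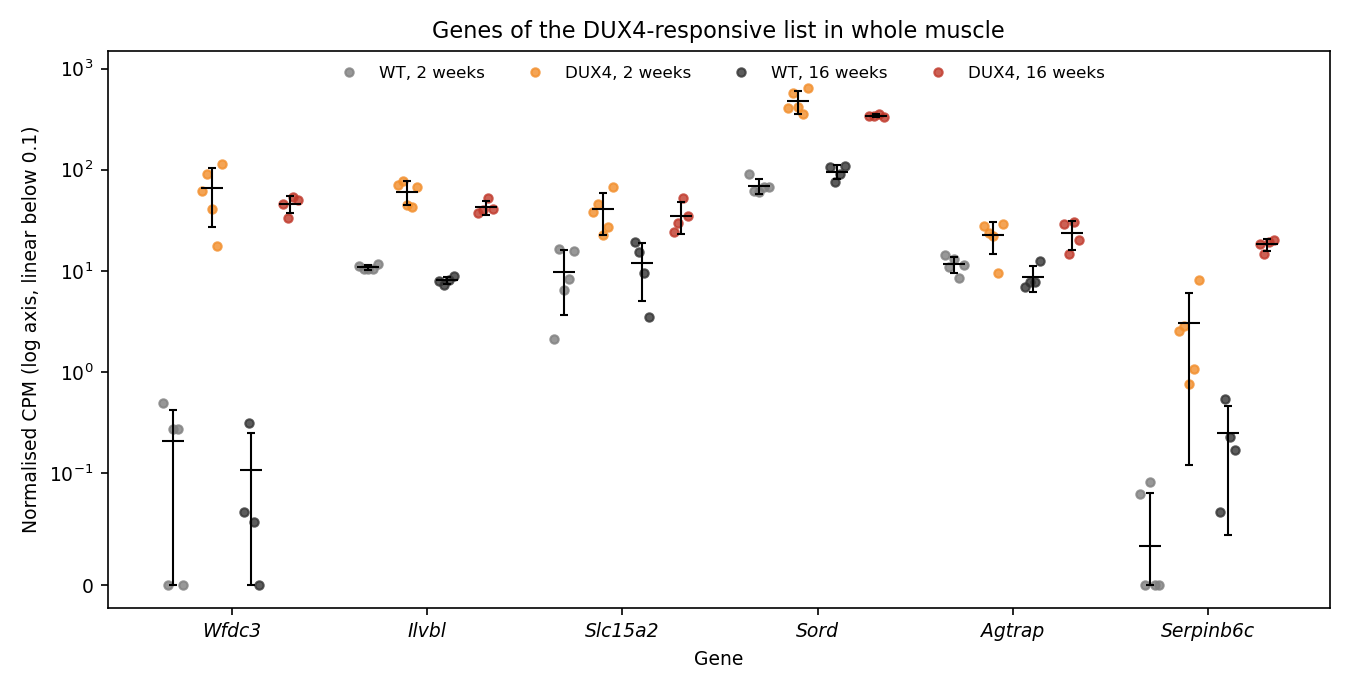
Normalised counts (CPM) of 6 genes of the DUX4-responsive list in whole muscle at 2 and 16 weeks, on an axis that is linear below 0.1 and logarithmic above it. Each point is a library and each bar the mean with its SD (n = 5, 5, 4 and 4); mean Wfdc3 was 65.2 and 45.9 CPM with DUX4 and 0.207 and 0.108 CPM in WT muscle.

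Genes of regenerating muscle rose at 2 weeks, and genes of mature fast fibres fell. Sln, which encodes the calcium pump regulator sarcolipin, rose from 9.36 ± 16.8 to 263 ± 146 CPM (log2 4.80 ± 0.99, adjusted p = 0.00335). Of the WT libraries, WT.2Weeks replicate 1 stood apart at 39.4 CPM, against a mean of 1.85 in the others. The neural adhesion gene Ncam1 rose by 1.40 ± 0.26. Of 14 regeneration genes 8 rose (9 adjusted over the list alone; median log2 1.98, list test adjusted p = 0.000752, adjusted p = 0.609 with an estimated correlation). Of 15 p53 targets 6 rose (9 up and 1 down adjusted over the list alone; median 0.951, adjusted p = 0.000752, and 0.609 with an estimated correlation), led by the RNA-binding gene Zmat3 (1.22 ± 0.19) and the cyclin gene Ccng1 (1350 ± 249 to 2680 ± 270 CPM). Of 19 cell cycle genes 5 rose (7 adjusted over the list alone; adjusted p = 0.00134, and 0.609 with an estimated correlation), among them the mitotic gene Cenpf (2.82 ± 0.35). Of 14 genes of denervated or wasting muscle 4 rose (7 adjusted over the list alone; adjusted p = 0.00509, and 0.77 with an estimated correlation). Actn3, which encodes the fast-fibre actinin, fell from 5470 ± 545 to 2020 ± 1150 CPM (log2 −1.44 ± 0.30, adjusted p = 0.00312), and the fast calcium pump gene Atp2a1 fell from 29700 ± 2860 to 16000 ± 5210 CPM. Of 16 fast-fibre genes 11 fell (12 adjusted over the list alone; adjusted p = 4.05e-07, and 0.609 with an estimated correlation). Of 14 genes of glycolysis and glycogen use 5 fell (8 adjusted over the list alone; adjusted p = 4.62e-05, and 0.609 with an estimated correlation), including the glycogen phosphorylase gene Pygm (−1.03 ± 0.23). Leaving out 1 library lowered these counts to 3 regeneration genes (WT.2Weeks replicate 4), 4 fast-fibre genes and 1 denervation gene (IDUX.2Weeks replicate 2), and 3 cell cycle and 2 glycolysis genes (IDUX.2Weeks replicate 1), and raised the glycolysis genes to 8 (IDUX.2Weeks replicate 4).

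Lists of vessel cell genes tested lower at 2 weeks at the preset correlation, with few genes called, and the lists for matrix and interferon were not called. Of 10 mural cell genes, which mark the cells that wrap small vessels, 3 fell (5 adjusted over the list alone; median −0.799, adjusted p = 0.00155, and 0.609 with an estimated correlation). None of 16 endothelial markers was called (0 adjusted over the list alone in edgeR, 3 lower with a term for 2 sets of libraries described below, 10 lower with limma voom), while the list test was lower (median −0.646, adjusted p = 0.0032, and 0.77 with an estimated correlation). Of 22 oxidative phosphorylation genes 4 fell (4 adjusted over the list alone, 10 with limma voom; adjusted p = 0.00067, and 0.77 with an estimated correlation), and of 9 mitochondrially encoded genes 1 fell (9 adjusted over the list alone, 9 with the term for sets; adjusted p = 0.00149, and 0.719 with an estimated correlation). Without IDUX.2Weeks replicate 4 there were 4 endothelial, 5 mural and 8 mitochondrially encoded genes lower, and without IDUX.2Weeks replicate 1 there were 0 mural, 0 mitochondrially encoded and 2 oxidative phosphorylation genes. The term for sets gave 5 mural genes lower. The 1 mitochondrially encoded gene called, mt-Co2 (log2 −1.361), stood at 6270 CPM in WT.2Weeks replicate 4, against a mean of 1060 in the other WT libraries. It lost its call in 6 refits without 1 library, that one included (adjusted p up to 0.274). Of 33 fibrillar matrix genes 4 rose (3 adjusted over the list alone, 2 without IDUX.2Weeks replicate 1, list test adjusted p = 0.488), including the collagen gene Col11a1 (2.44 ± 0.48) and the tenascin gene Tnc (1.90 ± 0.37). Of 20 interferon-response genes 1, Stat2, fell (log2 −0.54; list test adjusted p = 0.262), a call lost without IDUX.2Weeks replicates 1, 2 or 3 or WT.2Weeks replicate 2 (adjusted p up to 0.0757). The largest falls past 5 CPM included Chac1, a glutathione-degrading enzyme gene (−2.33 ± 0.50). Those of Cox6c2 (−8.47), Rorb (−5.96), Mir124-2hg (−3.57), AW822252 (−2.79) and Calb1 (−2.44) came from WT.2Weeks replicate 4, without which their adjusted p-values were 0.684, 0.236, 0.955, 0.835 and 0.737.

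In all, 2717 of 15396 genes were called at 2 weeks, 1721 higher and 996 lower with DUX4. Without IDUX.2Weeks replicate 2 the count was 1756. The libraries of both genotypes fell into 2 sets by their expression of genes that mark position in the body. Hoxd8, a homeobox gene, was at 57.1 ± 8.78 CPM in replicates 1 to 3 (n = 6) and 4.8 ± 0.508 CPM in replicates 4 and 5 (n = 4). Fitted alone, replicates 1 to 3 gave 3120 called genes and replicates 4 and 5 gave 16 (2259 at an unadjusted p under 0.05). Of 3008 genes called in replicates 1 to 3 and tested in both sets, 2797 changed in the same direction in replicates 4 and 5, and a term for the 2 sets gave 3192 calls.

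The comparison at 16 weeks asked the same question late in the course. Wfdc3 stood at 45.9 ± 8.87 CPM (SD, n = 4) with DUX4 and 0.108 ± 0.138 CPM (n = 4) in WT muscle, a log2 difference of 8.52 ± 0.74 (adjusted p = 4.34e-06), and Sord at 341 ± 9.87 against 95 ± 14.8 CPM. All 6 genes of the DUX4-responsive list rose again (6 adjusted over the list alone; median log2 2.12, adjusted p = 1.33e-11, and 0.0298 with an estimated correlation). The Slc15a2 call (1.55 ± 0.53, adjusted p = 0.0409) was lost in 6 of the 8 refits without 1 library of either group, namely without IDUX.16Weeks replicates 2, 3 or 4 or WT.16Weeks replicates 2, 3 or 4 (up to 0.119). Genes without a count in WT muscle were the amino acid transporter gene Slc6a20a (at least 37.2-fold higher), the cholecystokinin gene Cck (at least 22.7-fold), Lmntd2 (at least 21.5-fold) and the interleukin gene Iltifb (at least 18.6-fold). Entpd3, which encodes an enzyme that breaks down extracellular nucleotides, was at 56.6 ± 10.2 CPM against 0.0971 ± 0.194. The list of mouse homologues of genes scored in FSHD muscle biopsies had only 5 tested members in whole muscle, and C6, C7 and Ccna1 were among those not tested. Of the 5 tested, 4 rose (4 adjusted over the list alone, median 2.17, adjusted p = 0.0122, and 0.13 with an estimated correlation), and 1 rose without IDUX.16Weeks replicate 1. At 2 weeks 0 of these 5 were called in the edgeR fit, 2 with the term for sets or without WT.2Weeks replicate 1, and 2 with limma voom (list test adjusted p = 0.49).

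Matrix and skeletal tissue genes were higher at 16 weeks. Col1a1, the chain that makes up most of type I collagen, rose from 42.8 ± 17.5 to 193 ± 95.1 CPM (log2 2.18 ± 0.40, adjusted p = 0.000935), and the proteoglycan gene Bgn rose by 1.47 ± 0.22. Of 33 fibrillar matrix genes 16 rose (22 adjusted over the list alone; median 1.31, adjusted p = 1.83e-07, and 0.418 with an estimated correlation), and 10 rose without IDUX.16Weeks replicate 4. Of 23 matrix remodelling genes 8 rose (8 adjusted over the list alone; median 0.934, adjusted p = 0.00169, and 0.418 with an estimated correlation), including the protease gene Ctsk (3.21 ± 0.54). Of 10 bone and cartilage genes 6 rose (6 adjusted over the list alone; median 1.81, adjusted p = 0.00113, and 0.0364 with an estimated correlation). These included Cilp, a cartilage matrix gene (18.3 ± 8.51 to 253 ± 81.7 CPM; 3.79 ± 0.71, adjusted p = 0.00116), and Runx2, the transcription factor of bone formation (1.90 ± 0.33, adjusted p = 0.000606). Of 7 tendon cell genes 2 rose (4 adjusted over the list alone; adjusted p = 0.0128, and 0.435 with an estimated correlation), with Thbs4 at 184 ± 65.3 against 21.4 ± 4.66 CPM; 1 rose without IDUX.16Weeks replicate 1. Of 24 genes of transforming growth factor beta (TGF-beta) and bone morphogenetic protein (BMP) signalling 5 rose and 2 fell (5 up and 2 down adjusted over the list alone; median 0.364, adjusted p = 0.0484, and 0.418 with an estimated correlation), and Tgfb1 rose from 5.04 ± 1.4 to 13.9 ± 2.46 CPM.

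Interferon-response and antigen presentation genes were higher at 16 weeks. Oasl2, an antiviral gene induced by interferon, rose from 1.58 ± 0.789 to 5.87 ± 1.04 CPM (log2 1.93 ± 0.33, adjusted p = 0.000518), and Bst2 rose by 1.62 ± 0.29 (adjusted p = 0.000757). Of 20 interferon-response genes 13 rose (17 adjusted over the list alone; median 1.35, adjusted p = 3.13e-07, and 0.302 with an estimated correlation), and 7 rose without WT.16Weeks replicates 1 and 4. Of 7 genes of class II antigen presentation 6 rose (6 adjusted over the list alone; median 1.52, adjusted p = 0.00139, and 0.418 with an estimated correlation), H2-Ab1 from 6.79 ± 0.899 to 28.3 ± 9.22 CPM. Of 19 macrophage markers 3 rose (3 adjusted over the list alone; median 1.37, adjusted p = 0.00339, and 0.69 with an estimated correlation), with 1 without IDUX.16Weeks replicate 4 and 15 without WT.16Weeks replicate 1. Of 16 complement genes 2 rose (1 adjusted over the list alone; adjusted p = 0.0121, and 0.69 with an estimated correlation), with 1 and 4 without IDUX.16Weeks replicate 1 and WT.16Weeks replicate 1. The plasma cell gene Jchain rose by 1.94 ± 0.43, to 1.40 ± 0.531 CPM. Its list of 7 antibody-producing cell genes had 3 higher (1 without IDUX.16Weeks replicate 3, 5 without WT.16Weeks replicate 4) and was not called by camera at the preset correlation (adjusted p = 0.0867), but was by fry (0.00224).

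**Figure D2:**
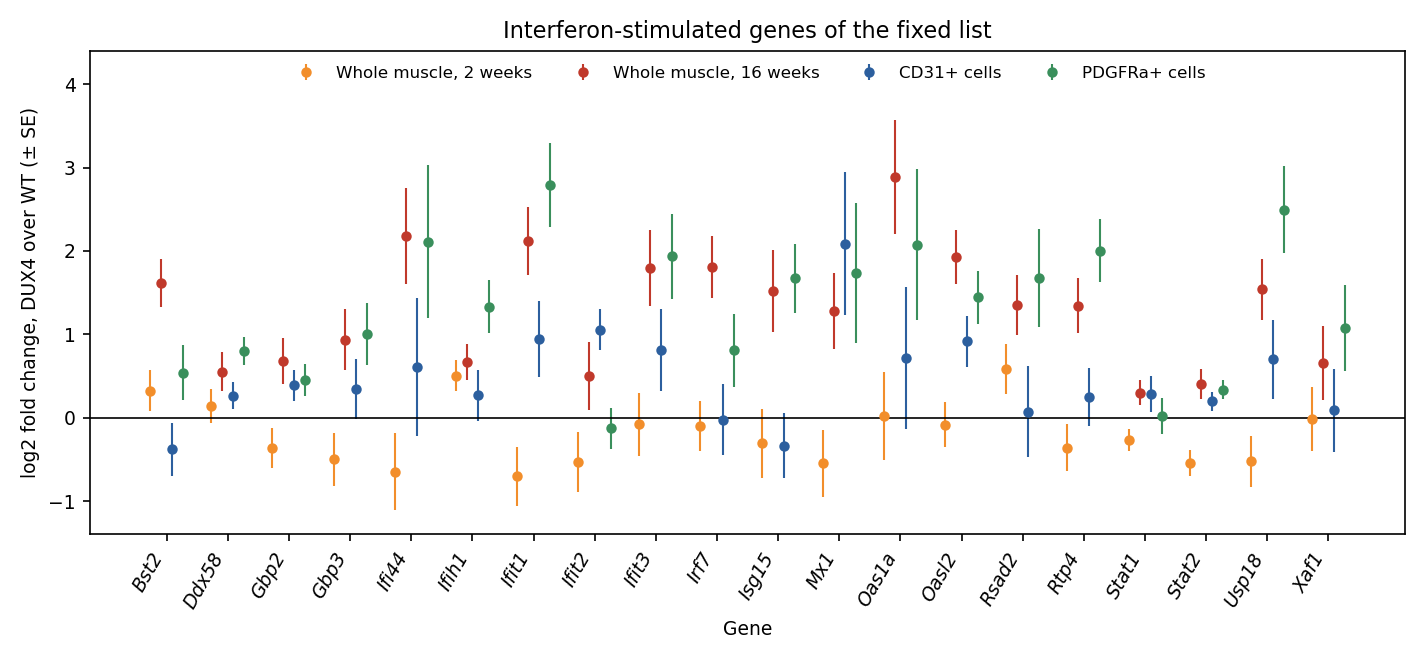
Log2 fold change, DUX4 over WT, of 20 interferon-response genes in the 4 comparisons, with bars showing the SE of each fitted value. Values above 0 number 5 of 20 in whole muscle at 2 weeks (median −0.288), 20 at 16 weeks (median 1.35), 17 in endothelial cells (median 0.313) and 19 in FAPs (median 1.39).

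Regeneration genes were also raised and fast-fibre genes lowered at 16 weeks. The embryonic myosin light chain gene Myl4 rose by 3.07 ± 0.69, Ncam1 by 1.38 ± 0.29 and the mitotic gene Cenpf by 3.88 ± 0.43 (adjusted p = 1.44e-05). Of 14 regeneration genes 8 rose (9 adjusted over the list alone; median 2.16, adjusted p = 0.000251, and 0.418 with an estimated correlation), with 4 without IDUX.16Weeks replicate 1 and 12 without WT.16Weeks replicate 1. Myh4, the fastest myosin heavy chain, fell from 51700 ± 6260 to 15900 ± 6570 CPM (log2 −1.71 ± 0.30, adjusted p = 0.00076). The muscle growth inhibitor gene Mstn fell from 115 ± 52 to 8.64 ± 7.03 CPM, and the glycolytic regulator gene Pfkfb3 fell by 3.17 ± 0.45. Of 16 fast-fibre genes 9 fell (10 adjusted over the list alone; adjusted p = 3.36e-05, and 0.418 with an estimated correlation). Of 14 glycolysis genes 5 fell (6 adjusted over the list alone; adjusted p = 0.00254, and 0.69 with an estimated correlation), with 1 without IDUX.16Weeks replicate 1 and 8 without WT.16Weeks replicate 1. The wasting gene Fbxo32 fell by 1.48 ± 0.32, and its denervation list was not called (3 of 14 higher, 3 lower, adjusted p = 0.47; 8 higher without WT.16Weeks replicate 1). Falls in the stress-hormone target Fkbp5 (−3.08) and in Lcn2 (−7.35) came from WT.16Weeks replicate 1, without which their adjusted p-values were 0.106 and 0.476. In all, 4097 of 15396 genes were called, 2169 higher and 1928 lower.

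The next comparison asked whether the DUX4 effect on whole muscle differed between the time points. Ifit1, an interferon-induced antiviral gene, changed more at 16 weeks than at 2 weeks by a log2 difference of 2.82 ± 0.54 (adjusted p = 0.0379), the cytokine gene Il1f9 by 3.88 ± 0.76 (adjusted p = 0.0379) and the cytoskeletal gene Pdlim2 by 2.46 ± 0.41 (adjusted p = 0.02). The kinase gene Nek6 (−2.01) and the early-response gene Csrnp1 (−2.39) changed the other way. Across 15396 genes 46 differed, 29 more positive and 17 more negative at 16 weeks, a balance that turned to 13 and 29 without WT.16Weeks replicates 1 and 4, to 24 and 33, 26 and 27, 12 and 14, and 21 and 22 without WT.16Weeks replicate 4, WT.16Weeks replicate 1, WT.2Weeks replicate 2 or IDUX.2Weeks replicate 4, and to 135 and 135 with limma voom. The number was 8 without IDUX.16Weeks replicate 3, 11 without IDUX.16Weeks replicate 4 or WT.2Weeks replicate 1, and 57 without WT.16Weeks replicate 4, and a term for the 2 sets of 2-week libraries gave 137, 90 more positive and 47 more negative. Of the 8 named genes only Cep112it (2.70 ± 0.40, adjusted p = 0.0113) kept its call in every such refit. Between the times 19 lists were called at the preset correlation, 0 with an estimated correlation and 5 with fry, and 6 of the 19 are described here. The interferon list differed (1 of 20 genes, 0 without IDUX.2Weeks replicate 1, 15 adjusted over the list alone; median 1.57, adjusted p = 7.09e-18, and 0.0736 with an estimated correlation), and so did the fibrillar matrix list (0 of 33 in edgeR, 9 adjusted over the list alone; median 1.23, adjusted p = 8.52e-10, and 0.311 with an estimated correlation). Among the other lists called more positive at 16 weeks were antibody-producing cell genes (0 of 7 called, 3 adjusted over the list alone; median 2.58, adjusted p = 0.000356, and 0.138 with an estimated correlation), tendon genes (1 of 7, 1 adjusted over the list alone, 0 without IDUX.2Weeks replicate 1; 1.70, 0.000955, and 0.311 with an estimated correlation) and complement genes (0 of 16, 0 adjusted over the list alone; 1.28, 0.000183, and 0.459 with an estimated correlation). The immediate early list was more negative (0 of 16 called, 4 adjusted over the list alone; −1.17, adjusted p = 0.000253, and 0.311 with an estimated correlation). The DUX4-responsive list was not called (0 of 6 genes, 1 down adjusted over the list alone; median −0.049, adjusted p = 0.49). Both time points called 1034 genes higher and 581 lower, against 242 and 125 if the calls were independent, and 8 genes in opposite directions. Across all tested genes, which are not independent replicates, the log2 changes correlated with Pearson's r = 0.569 and Spearman's rho = 0.475.

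In the endothelial libraries, matrix and FAP genes were higher with DUX4. Smoc2, a matrix gene abundant in FAPs, rose from 386 ± 69.3 CPM (SD, n = 3) to 1750 ± 180 CPM (n = 4), a log2 difference of 2.18 ± 0.17 (adjusted p = 1.79e-06). Lum, which encodes the collagen-binding protein lumican, rose from 228 ± 72.2 to 1080 ± 175 CPM (2.25 ± 0.20, adjusted p = 6.43e-06), and Pdgfra, the FAP sorting marker (chosen after its values were seen), from 46 ± 20.3 to 151 ± 33.8 CPM. Of 33 fibrillar matrix genes 20 rose (24 adjusted over the list alone; median 1.2, adjusted p = 3.37e-41, and 0.00434 with an estimated correlation). Of 24 remodelling genes 8 rose (11 adjusted over the list alone; adjusted p = 7.02e-15, and 0.00591 with an estimated correlation), among them Mmp2 (1.83 ± 0.14) and Ctsk (2.38 ± 0.22). Of 16 FAP markers 10 rose (12 up and 1 down adjusted over the list alone; median 1.54, adjusted p = 4.41e-28, and 0.00289 with an estimated correlation). In FAPs themselves the same list was not called (1 of 16 higher, adjusted p = 0.874). Of the 601 genes called higher in endothelial cells that had a signal in WT cells, 545 were more abundant in the FAP libraries than in the endothelial libraries. Over 23 genes at least 16 times higher in FAPs than in WT endothelial cells, the level relative to FAPs was 16.9% with DUX4 and 4.99% in WT cells. This choice of genes holds down the WT level. Over 334 genes at least 4 times higher in FAPs, the levels were 25.5% and 12.2%.

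**Figure D3:**
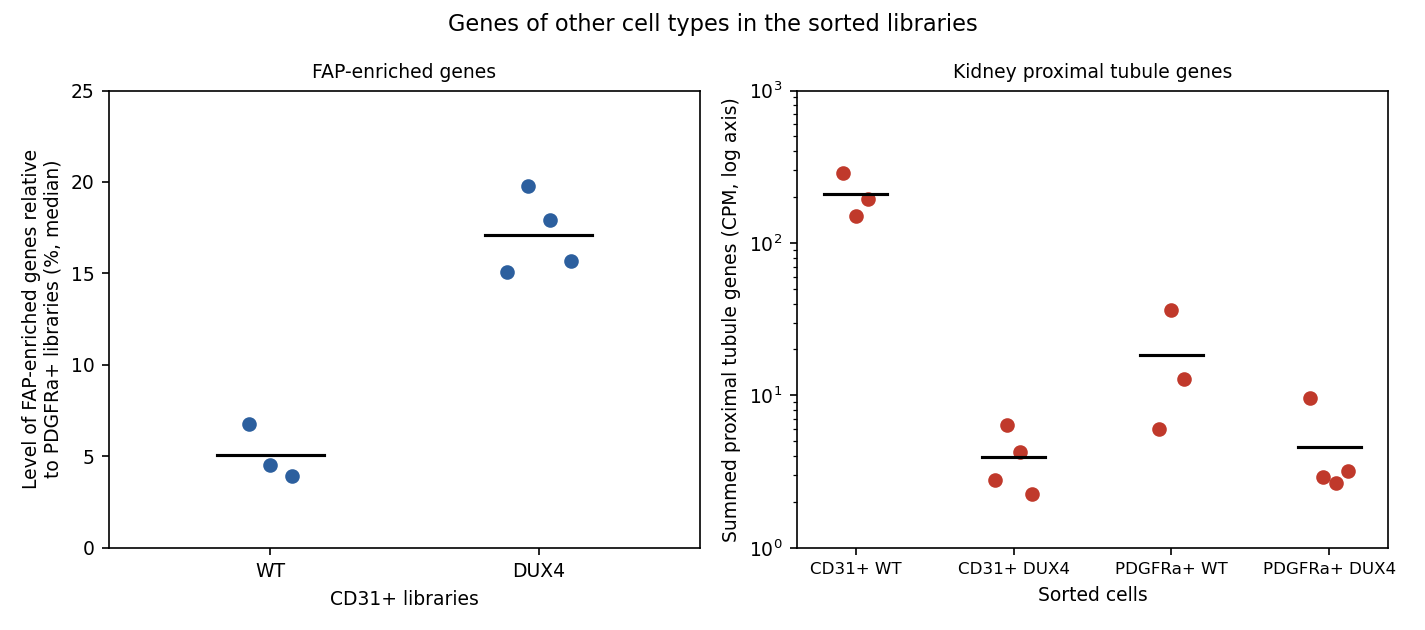
Left, the median level of 23 FAP-enriched genes in each CD31-sorted library as a percent of their level in the PDGFRa-sorted libraries. These genes were chosen as at least 16 times higher in FAPs than in CD31WT, which in part fixes the low CD31WT level. Right, the summed CPM, on a log axis, of 25 kidney proximal tubule genes in each sorted library, chosen for a mean under 1 CPM in whole muscle and in CD31DUX, which in part fixes the low CD31DUX level. Points are libraries and lines are group means; the left values run from 15.1% to 19.8% with DUX4 and from 3.92% to 6.76% in WT cells, and the right means are 210 CPM in CD31WT and 3.93 CPM in CD31DUX, against 742 and 339 CPM over all 36 genes of the list.

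Genes of signalling, complement and muscle were also higher in the endothelial libraries with DUX4. Whether endothelial cells themselves expressed the muscle and immune genes was not tested. Pgf, the gene for placental growth factor, which acts on vessels, rose from 27.2 ± 11 to 117 ± 23.2 CPM (2.11 ± 0.29, adjusted p = 0.000273). Of 16 Wnt genes 3 rose (5 adjusted over the list alone, median 0.717, adjusted p = 0.0011, and 0.0364 with an estimated correlation), with the secreted Wnt inhibitor gene Sfrp4 at 2.65 ± 0.42. For Sfrp4 the larger FAP share estimated below predicted a rise of 1.4. Of 17 complement genes 5 rose (5 adjusted over the list alone; adjusted p = 1.01e-10, and 0.0922 with an estimated correlation), with C1s1 at 1.57 ± 0.14, and 10 rose without CD31WT replicate 1. Of 24 TGF-beta and BMP genes 9 rose and 1 fell (12 up and 1 down adjusted over the list alone; adjusted p = 4.3e-05, and 0.0866 with an estimated correlation). Mstn, without a count in WT cells, was at least 36.6-fold higher (6.1 ± 1.92 CPM), and sarcolipin (Sln) rose by 3.69 ± 0.55. The dendritic cell integrin gene Itgax was at 14 ± 5.3 against 0.0373 ± 0.0646 CPM. Macrophage markers (1 of 19 higher; median 1.63, adjusted p = 0.000526, and 0.374 with an estimated correlation), class II genes (1 of 7, 7 adjusted over the list alone; 2.27, 0.000113, and 0.196 with an estimated correlation) and fast-fibre genes (3 of 16, 12 adjusted over the list alone; 1.54, 1.74e-07, and 0.195 with an estimated correlation) were higher as lists. Without CD31WT replicate 1, 5 macrophage and 4 class II genes rose, and without CD31DUX replicate 1 or 2 there was 1 fast-fibre or 0 class II genes. For the bone and cartilage list (2 of 11 higher) the median was 0.336, the mean −0.00338 and the test positive (adjusted p = 0.0399, and 0.196 with an estimated correlation). The lymphatic endothelial gene Lyve1 rose from 86.3 ± 29.9 to 657 ± 147 CPM (2.93 ± 0.64, adjusted p = 0.0217), a call lost without CD31DUX replicate 3 or CD31WT replicate 1 or 3 (adjusted p up to 0.112). DUX4-responsive genes were not called (0 of 6 in the edgeR fit, 1 without CD31WT replicate 1, and 0 with limma voom; list test adjusted p = 0.477).

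Genes of vessel walls, nerves and kidney were lower in the endothelial libraries with DUX4. Whether endothelial cells themselves expressed the mural, Schwann and red cell genes was not tested, and the kidney genes are taken up below. Acta2, the smooth muscle actin gene, fell from 324 ± 19.9 to 122 ± 29.5 CPM (log2 −1.4 ± 0.23, adjusted p = 0.00149), and the smooth muscle myosin gene Myh11 fell by 1.68 ± 0.29. Of 10 mural genes 3 fell (6 adjusted over the list alone; median −1.09, adjusted p = 2.91e-07, and 0.0112 with an estimated correlation), and of 8 Schwann cell genes 1 fell (0 without CD31DUX replicate 1, 5 adjusted over the list alone; adjusted p = 0.00188, and 0.038 with an estimated correlation). Of 16 endothelial markers 2 fell (3 adjusted over the list alone, 9 with limma voom; median −0.595, adjusted p = 6.67e-06, and 0.214 with an estimated correlation), with 1 in each refit without 1 library of either group. The water channel gene Aqp1 fell by 1.22 ± 0.23. The sorting marker Pecam1, chosen after its values were seen, did not pass the threshold (−0.43 ± 0.18, adjusted p = 0.231). Haemoglobin and other red cell genes were lower as a list (0 of 5 called, 4 adjusted over the list alone; median −2.09, adjusted p = 0.000753, and 0.251 with an estimated correlation). The largest falls were of genes of the kidney proximal tubule. Kap fell from 131 ± 120 to 1.35 ± 1.9 CPM (−6.63 ± 1.33, adjusted p = 0.0147), a call lost with only the 2 groups fitted (adjusted p = 0.0527). Ugt2b38 was at least 53.3-fold lower, with no count with DUX4. In all, 863 of 17008 genes were called, 633 higher and 230 lower, and 520 without CD31WT replicate 3. Among genes no higher in the FAP libraries the balance turned to 69 higher and 184 lower.

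In FAPs, interferon-response genes were higher with DUX4. Cxcl9, a chemokine gene induced by interferon gamma, rose from 8.6 ± 1.17 CPM (SD, n = 3) to 75.1 ± 34.5 CPM (n = 4), a log2 difference of 3.13 ± 0.34 (adjusted p = 0.00012). The interferon-induced transcription factor gene Batf2 rose by 3.82 ± 0.59 (adjusted p = 0.00169), and Ifi206, without a count in WT cells, was at least 36.7-fold higher (6.78 ± 3.75 CPM). Ifit1 rose from 84.6 ± 55.9 to 585 ± 264 CPM (2.79 ± 0.50, adjusted p = 0.00963, and 0.0524 without PDGWT replicate 2). Of 20 interferon-response genes 7 rose (11 adjusted over the list alone; median 1.39, adjusted p = 6.66e-17, and 0.109 with an estimated correlation), with 0 in edgeR without PDGWT replicate 2 and 12 without PDGWT replicate 3. Thbs4, a matrix gene of tendon and injured muscle, rose from 777 ± 164 to 2330 ± 202 CPM (1.58 ± 0.18, adjusted p = 0.00012), Tnc by 1.91 ± 0.32, Thbs1 by 1.23 ± 0.20 and the transcription factor gene Runx1 by 1.35 ± 0.16 (adjusted p = 0.000208). Of 33 fibrillar matrix genes 5 rose (12 adjusted over the list alone; median 0.378, adjusted p = 1.28e-09, and 0.182 with an estimated correlation), with 3 without PDGDUX replicate 2. Of 24 remodelling genes 3 rose (5 up and 1 down adjusted over the list alone; adjusted p = 4.56e-06, and 0.109 with an estimated correlation), with 1 without PDGWT replicate 2.

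Pgf, in contrast to its rise in endothelial cells, fell in FAPs from 101 ± 26.8 to 8.25 ± 2.33 CPM (log2 −3.61 ± 0.29, adjusted p = 6.08e-06). The amino acid transporter gene Slc38a4 was at least 31.5-fold lower, with no count with DUX4 and 8.97 ± 1.71 CPM in WT cells (adjusted p = 4.8e-05). The sialyltransferase gene St8sia6 fell by 5.69 ± 0.51 (adjusted p = 1.68e-05), the Wnt effector gene Lef1 by 4.75 ± 0.97 and Dlk1, a gene that restrains fat cell formation, by 3.77 ± 0.70. The adhesion gene Tenm2 was at 0.0214 ± 0.0428 against 11.7 ± 1.53 CPM. Of 12 adipogenic genes 3 fell (2 up and 5 down adjusted over the list alone, median −0.546, adjusted p = 0.00891, and 0.109 with an estimated correlation). They were Dlk1, the lipid carrier gene Apoe (−1.01 ± 0.19) and Fabp4. Since Dlk1 restrains fat cell formation and Fabp4 is also on the endothelial list, these falls show no single change of fat cell formation. Endothelial and mural genes were lower, with Vwf, the gene for von Willebrand factor, at −1.84 ± 0.32 and Pecam1 at 21.3 ± 2.63 against 44.8 ± 16.5 CPM. Of 16 endothelial markers 6 fell (11 adjusted over the list alone; median −1.12, adjusted p = 2.42e-13, and 0.109 with an estimated correlation), and of 10 mural genes 2 fell (5 adjusted over the list alone; adjusted p = 0.000478, and 0.109 with an estimated correlation). The mural count was 1 without PDGWT replicate 3. Schwann cell genes were also lower as a list (1 of 8 called, 0 without PDGDUX replicate 3; median −0.531, adjusted p = 0.0113, and 0.109 with an estimated correlation). No list call in FAPs held with an estimated correlation (0 of the 14). DUX4-responsive genes were not called (0 of 6 in edgeR, list test adjusted p = 0.121). In all, 510 of 17008 genes were called, 209 higher and 301 lower, though 259 higher and 224 lower with only the 2 FAP groups fitted, 119 and 99 among genes no higher in endothelial libraries, and 234 and 262 with relative log expression factors. The count was 339 without PDGDUX replicate 4, 291 without PDGWT replicate 1 and 326 without PDGWT replicate 2. The 2 FAP groups did not overlap in depth (11 to 13.7 M with DUX4, 16.6 to 18.9 M in WT). Nor did they in genes above 0 (17742 to 18233 and 19817 to 20484). The effect of either on these calls was not tested.

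The last comparison asked whether the DUX4 effect differed between FAPs and endothelial cells. Pgf, chosen after its values were seen, differed by a log2 value of −5.72 ± 0.41 (adjusted p = 5.14e-06), falling in FAPs and rising in endothelial cells. Megf6, a gene for an epidermal growth factor repeat protein, differed by −6.95 ± 0.95 (adjusted p = 0.000988) and the checkpoint kinase gene Chek2 by −7.90 ± 1.46 (adjusted p = 0.0127). Slc38a4, with no count in FAPs with DUX4, rose in endothelial cells (1.98 ± 0.40, adjusted p = 0.0115) and differed too (adjusted p = 1e-04). In all, 383 of 17008 genes differed, 94 more positive in FAPs and 289 more negative, with 238 without PDGWT replicate 1 and 250 without PDGWT replicate 2. At the preset correlation 10 lists were called, 4 of them described here. FAP markers had a more negative DUX4 effect in FAPs than in endothelial cells (9 of 16, 14 down and 1 up adjusted over the list alone, median −1.43, adjusted p = 8.79e-22, and 0.00992 with an estimated correlation). That list was not called in FAPs themselves and was higher in the endothelial libraries with DUX4. Wnt genes were also more negative (2 of 16, 5 adjusted over the list alone, median −1.4, adjusted p = 2.6e-05, and 0.0113 with an estimated correlation). The Wnt count was 0 without CD31DUX replicate 2 and 4 without CD31WT replicate 1. Fibrillar matrix genes were more negative (10 of 33, 12 adjusted over the list alone, median −0.688, adjusted p = 4.02e-12, and 0.205 with an estimated correlation), against a median of −0.124 over all genes. They tested higher in both cell types at the preset correlation, with the larger median rise in endothelial cells. Interferon genes were more positive in FAPs as a list (0 of 20 called in edgeR, 2 up and 1 down adjusted over the list alone; 0.952, adjusted p = 9.43e-06, and 0.492 with an estimated correlation). Both cell types called 55 genes higher and 40 lower, against 7.78 and 4.07 if independent, and 13 in opposite directions. Whole muscle at 16 weeks shared 205 higher calls with endothelial cells (81.3 if independent) and 71 with FAPs (27.1), and 21 and 19 lower calls (25.8 and 36.9). Of the 601 endothelial rises with a signal in WT cells, 545 were of genes more abundant in the FAP libraries. For such genes neither the overlaps nor the differences can separate a response of endothelial cells from FAP RNA in the CD31 libraries.

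**Figure D4:**
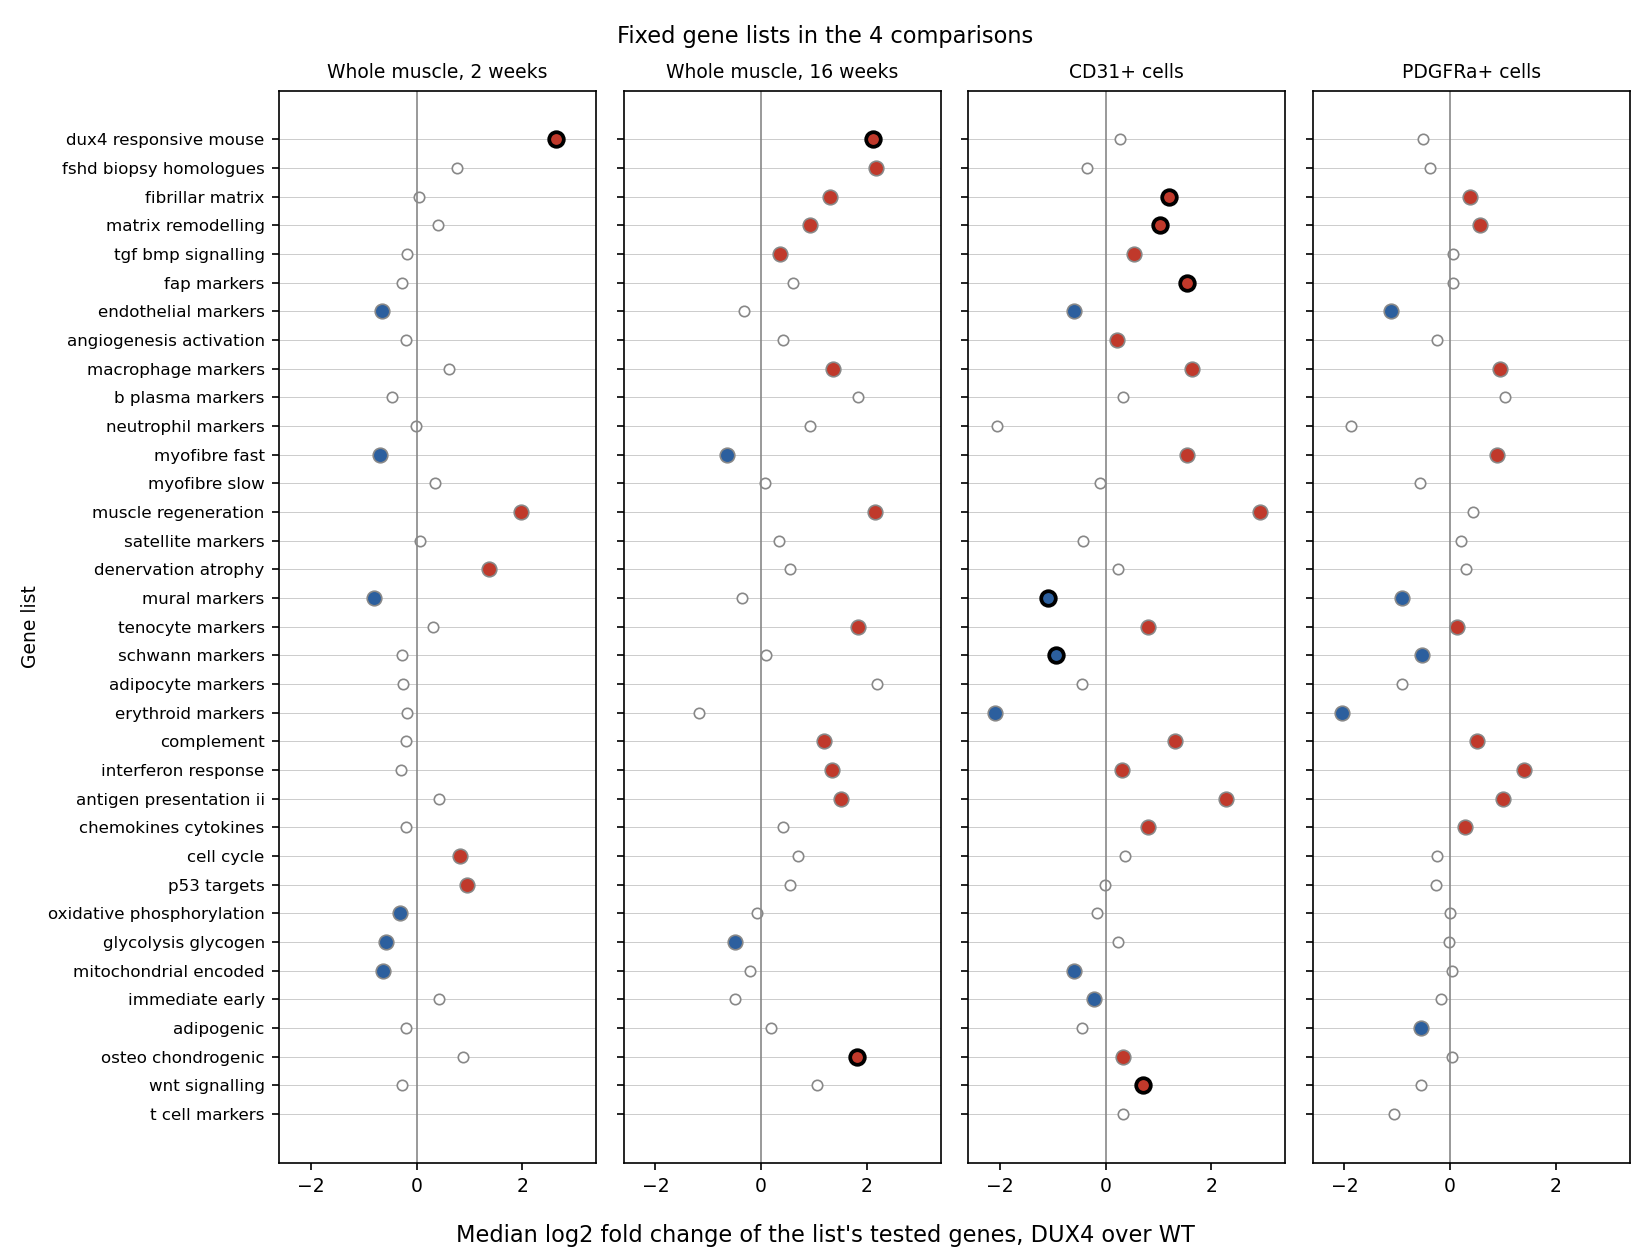
Median log2 fold change, DUX4 over WT, of 35 fixed gene lists in 4 panels, for whole muscle at 2 and 16 weeks, endothelial cells and FAPs. Points are filled in red (higher) or blue (lower) where the preset-correlation test gave an adjusted p under 0.05, in 11, 14, 21 and 14 lists, and outlined in black where the estimated-correlation test did, in 1, 2, 6 and 0.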

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

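The tests of other splits of the libraries were chosen before the results were seen, and all tests of explanations (FAP RNA, kidney RNA and position in the body, each with its rivals) were chosen only after the result was seen. The tests of a rise of matrix genes alone, of a loss of kidney genes and of depth were each written again in further forms after the outcome of the first form was known, and all their values are given.

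The first pattern was the higher level of FAP and matrix genes in the DUX4 endothelial libraries. Tables argue against a rise of the genes of the 2 fixed matrix lists alone. Once the rise that a larger FAP share predicts was taken off, 27 listed matrix genes exceeded 284 other FAP-enriched genes by a median log2 of only 0.031 (bootstrap −0.0694 to 0.153). The first form of this test, with 1 matrix gene against 22 others, gave 0.329 and decided nothing. The other genes can include matrix genes outside the lists, so a wider rise of matrix genes would lift both sides and was not tested. RNA or cells of the FAP population in the CD31 sort are a candidate explanation, although the gate on CD31 should remove such cells. All 23 genes at least 16 times higher in FAPs than in WT endothelial cells were positive. Their implied FAP share was 3.43 times as high with DUX4 (15.1%, 19.8%, 17.9% and 15.7% in the 4 DUX4 libraries, and 6.76%, 4.51% and 3.92% in the 3 WT libraries). Over 334 genes at least 4 times higher it was 2.12 times as high (25.5% and 12.2%). Both choices rest on a low WT endothelial level, which itself favours a positive sign and a higher ratio. Of the 601 genes called higher with a signal in WT cells, 371 had at least 0.5 of their rise predicted by that share and 317 exceeded the prediction by 2 SE, an excess that the choice of called genes favours, and genes low in FAPs such as Mmrn1 (0.189 CPM in FAPs with DUX4) and Pgf (8.25 CPM), outside this pattern, cannot have risen by it. What stays open is whether more FAPs or their RNA entered the sort, and whether endothelial cells also changed some of the FAP and matrix genes.

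The second pattern was the higher level of kidney genes in the WT endothelial libraries. Tables argue against a loss of these genes by endothelial cells with DUX4: WT muscle, which holds endothelial cells, had the 19 genes called lower at a median of 0.0341 times the level that its endothelial markers predicted (quartiles 0 and 0.382, against 0.716 and 1.54 for 16 endothelial markers), with Kap at 0.00624 CPM where 7.6 was predicted and Miox at 0 where 1.65 was, although Cyp2e1 (8.2 against 0.525) and Gatm (9.08 against 4.57), 2 of the 19, exceeded the prediction and brought the summed level to 19.9 of 24.6 CPM. The earlier tests of a loss, in FAPs, were weaker: WT over DUX4 libraries gave a ratio of 1.31 over all 36 genes of the list, as a loss predicted, and of 4 with overlapping libraries over 25 of them, leaving out 11 that muscle or DUX4 endothelial libraries also express. Kidney RNA or cells in the WT preparations are a candidate explanation: 57.6% of the tested proximal tubule genes (19 of 33) were called lower with DUX4, while of 7 tested genes of other kidney segments 0 were lower and 1 was higher in edgeR. These lists were written after the calls had been seen, so the shares are no independent test. How kidney material would have passed a CD31 sort, and whether sorting itself induced such genes in WT cells, stays open.

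The third pattern was the split of the 2-week muscle libraries into replicates 1 to 3 and replicates 4 and 5, in both genotypes. Tables argue against depth as the whole cause, since with all 10 libraries thinned to 10.6 M counts 83.1% of the 1482 genes called between the sets were still called (only 1 of the 4 libraries of replicates 4 and 5 lay within the depths of replicates 1 to 3). The called share of positional genes was 5.29 times that of the other genes. That ratio cannot decide on a library or sequencing batch alone, since the sets were themselves recognised by such genes. Muscles from different positions in the body are a candidate explanation: 56.2% of 32 positional genes were called between the sets, against 10.6% of other genes (one-sided Fisher p = 3.57e-10). This p-value is no independent support, since the list was written after the calls had been seen. Tbx1, a head and neck muscle regulator, was at 1.47 ± 0.687 CPM in replicates 1 to 3 and 50 ± 8.73 CPM in replicates 4 and 5, and Irx5 at 18.9 ± 2.17 and 0.254 ± 0.261 CPM. A batch, alone or coinciding with the muscle taken, stays open. So does any effect on the comparison of times, since the 16-week libraries resembled neither set in all 3 genes (Hoxd8 39.8 ± 9.59, Tbx1 5.43 ± 1.76, Irx5 0.397 ± 0.334 CPM).

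When the same libraries were split in other ways, no other split drawn called as many genes in the 4 comparisons of DUX4 with WT. With the real split included, 1 of 100 splits drawn gave as many genes at 2 weeks (2717, highest other 2005). It was 1 of 35 at 16 weeks (4097, 223), in endothelial cells (863, 43) and in FAPs (510, 156). With 35 splits the share can go no lower than 1 of 35. Such splits cannot separate DUX4 from a difference in preparation that follows genotype. The 2-week split with 2005 genes set IDUX.2Weeks replicates 1, 2, 3 and 5 and WT.2Weeks replicate 1 against the others. A term for the 2 sets gave 3192 for the real split. The other splits were not fitted with that term, so 3192 has no counts of other splits to be set against. For the interactions such splits also break up the DUX4 effect within each time or cell type, so they do not test the difference itself. Between cell types 1 of 100 gave as many (383; 262) and between times 2 of 100 (46; 1889). The split with 1889 kept the 16-week groups whole and mixed the 2-week ones, so that the DUX4 effect at 16 weeks by construction appears as a difference, the structure of the samples that this count points to.

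Some libraries stood apart from their group by the gap to the nearest other library. CD31DUX replicate 1 had 18315 genes above 0 and IDUX.16Weeks replicate 2, the shallowest, had 19122. In WT.16Weeks replicate 1 the 10 most abundant genes took 19.5% of the counts and mitochondrial genes 11.3%. Among the named genes WT.16Weeks replicate 1 stood apart in 8, WT.2Weeks replicate 4 in 7, and IDUX.2Weeks replicate 4 and WT.2Weeks replicate 1 in 5 each. Of 391 such tests of named genes 56 (14.3%) passed. Chance passes about 1 in 20 where values are normally distributed. That rate need not hold for CPM near 0 or for genes named for their extreme changes.

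Interaction tests gave 46 genes whose DUX4 effect differed between times and 383 between cell types. Named among the former were Il1f9 (3.88), Ifit1 (2.82), Cep112it (2.70), Pdlim2 (2.46), Vkorc1l1 (−1.32), Nek6 (−2.01), Mss51 (−2.28) and Csrnp1 (−2.39), as log2 differences of 16 weeks minus 2 weeks. Named among the latter, FAPs minus endothelial cells, were Hdac9 (6.61), Fxyd2 (2.77), Grip2 (2.55), Picalm (2.22), Megf6 (−6.95), Gpr165 (−7.71), Chek2 (−7.90) and Slc38a4 (−12.16, a fitted value that is no bound, since the FAPs with DUX4 had no count).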

How the results depend on the processing

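The term for the 2 sets of 2-week libraries, each set alone, leaving out WT.16Weeks replicates 1 and 4 together and the restrictions by gene were chosen after seeing the data; the other settings were not. Counts of called genes stayed within 1.5 times of the reported count under relative log expression factors and the stricter filter in all 6 comparisons and with only the 2 groups fitted in the 4 where that was run; the exceptions under other settings follow, and the cause was not tested unless stated. Without WT.16Weeks replicates 1 and 4 the balance of the difference between times turned, and so did that in FAPs with only the 2 groups fitted (259 higher, 224 lower) and those in endothelial cells and FAPs among genes no higher in the other cell type. With limma voom the count was 4351 (2717 reported) at 2 weeks and 270 (46) for the difference between times. With DESeq2, whose false calls on simulated counts were more frequent, it was 466 (46), 1460 (863) in endothelial cells, 1038 (510) in FAPs and 824 (383) for the difference between cell types. With no filter the difference between times gave 19. A covariate of Y-linked counts gave 2483 (4097) at 16 weeks, 11 (46) for the difference between times and 467 (863) in endothelial cells. This covariate need not follow sex. In IDUX.16Weeks replicate 3, for example, Uty was at 72.1 CPM, while Ddx3y was at 0.836 CPM and Xist at 171 CPM. Requiring an absolute log2 fold change of at least 1, which by construction removes genes, left 1132 at 2 weeks, 1843 at 16 weeks and 555 in endothelial cells. Of the 2-week sets, replicates 4 and 5 alone, with fewer libraries, gave 16, and a term for the sets gave 137 genes for the difference between times. Without WT.16Weeks replicates 1 and 4 there were 3611 at 16 weeks and 42 for the difference. Restricted to genes no higher in FAPs, endothelial calls were 253 (69 higher, 184 lower), and FAP calls among genes no higher in endothelial cells were 218 (119 and 99), both by construction fewer. Outside the kidney lists endothelial calls were 843. Leaving out 1 library at a time gave 1756 (without IDUX.2Weeks replicate 2) to 3607 genes at 2 weeks, 3172 to 4346 at 16 weeks, 8 to 57 for the difference between times, 520 (without CD31WT replicate 3) to 1091 in endothelial cells, 291 (without PDGWT replicate 1) to 555 in FAPs and 238 (without PDGWT replicate 1) to 541 for the difference between cell types. Over these refits 20 of 57 named calls were lost at least once at 2 weeks, 15 of 70 at 16 weeks, 7 of 8 between times, 12 of 54 in endothelial cells, 22 of 47 in FAPs and 5 of 8 between cell types. The 15 leave out Lcn2, which lost its call and reversed without WT.16Weeks replicate 1. Some named genes that were not called changed sign, such as Col1a1 (−0.25 to 0.67) and Comp (−0.56 to 1.66) at 2 weeks. Of those that were called 2 reversed: Mir124-2hg in 2-week replicates 1 to 3 alone (0.35, against −3.57), and Lcn2 at 16 weeks with limma voom (0.53, against −7.35), without WT.16Weeks replicates 1 and 4 (0.85) and over the refits without 1 library (−7.77 to 1.17, the latter without WT.16Weeks replicate 1, which held 209 CPM). The list tests depended most on the correlation assumed between genes: with an estimated correlation 1 list was called at 2 weeks (11 reported), 2 at 16 weeks (14), 6 in endothelial cells (21), 0 in FAPs (14), 0 between times (19) and 2 between cell types (10), and fry called 5 between times. With an unadjusted p under 0.01, which admits more genes in sorted cells and fewer in 16-week muscle, FAPs and endothelial cells shared 145 higher and 88 lower calls (55 and 40), FAPs and 16-week muscle 136 and 46 (71 and 19), and endothelial cells and 16-week muscle 53 lower (21). Depth set the floor at 0.145 to 0.494 CPM per library, and lower levels could not be told from 0.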

Other observations

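The features below were chosen only after their values were seen, and no explanation of them was tested. In endothelial cells 4 genes of lymphatic vessels were higher with DUX4: Mmrn1 (981 ± 149 CPM, n = 4, against 122 ± 39.2 CPM, n = 3; log2 3.01 ± 0.23, adjusted p = 1.79e-06; mean in FAPs with DUX4 0.189 CPM), Reln (2.14 ± 0.27, adjusted p = 0.000157), Flt4 (1.74 ± 0.43, adjusted p = 0.0343) and Ccl21a (2.57 ± 0.66, adjusted p = 0.0489). Prox1, the regulator of this cell type, did not pass the threshold (1.55 ± 0.49, adjusted p = 0.0939).

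Sex is not in the labels. Xist, the RNA of the inactive X chromosome, was at 1.18 CPM in WT.16Weeks replicate 4 and at 142 to 302 CPM in the other 17 whole-muscle libraries. Of the Y-linked genes, Ddx3y and Eif2s3y had no count in WT.16Weeks replicate 4, as in replicates 1 and 2, while Kdm5d was at 2.21 CPM (2.23 and 1.39 in those 2) and Uty at 7.52 CPM (1.42 and 0.598), below the 72.1 and 10.4 CPM of IDUX.16Weeks replicates 3 and 1. Its Kdm6a level was 14.8 CPM (20.1 to 40.7 in the others), Kdm5c 38.7 (42.5 to 58), Eif2s3x 114 (160 to 237) and Ddx3x 242 (189 to 412).

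WT.16Weeks replicate 1 held 394 CPM of Cdkn1a (mean of the other WT 16-week libraries 29.4), 470 of Fkbp5 (36.1), 209 of Lcn2 (0.115) and 1430 of Plin4 (425). WT.2Weeks replicate 4 held 211 CPM of Rorb (1.25) and 133 of Cox6c2 (0.107). Endothelial markers summed to 274 ± 60.1 CPM in the FAP libraries with DUX4 (214 to 350, n = 4) and to 544 ± 142 in those of WT (446 to 707, n = 3).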
